A study of Homo sapiens with 23 samples.

How the data were processed

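Gene expression was measured on Affymetrix human genome arrays, 1 array for each of 23 RNA samples from MCF-7 cells, an established human breast cancer line that expresses estrogen receptor α. The values are MAS5 signal intensities on a linear scale, 1 for each of 22283 probe sets, deposited by the authors in a single table. MAS5 is named per the submitters' processing notes, and its version, target value and detection calls are not given in the sources used here. The 2% trimmed mean of the deposited intensities lay between 150.057 and 150.064 on every array, so each array had been scaled to a shared mean and no further scaling was applied. Median signals ranged from 35.7 to 47.6 between arrays. The number of arrays limits the precision of every value, and no pair of arrays held identical values (0 pairs).

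Probe sets were named through the platform annotation, dated 2016, and symbols were updated by Entrez identifier in a RefSeq gene table of assembly GRCh38.p14. Of the probe sets, 19065 carried 1 gene symbol, 1043 carried several and 2107 carried none in the annotation, and 68 were Affymetrix controls. An identifier match was found for 19053 of the 19065, and the other 12 kept the symbol of the annotation. Probe sets with several symbols or none were left out of all tests, which left 11963 named genes.

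Signals were transformed as log2(signal + 16). Probe sets whose mean over the 23 arrays fell below the 30th percentile, at a mean signal of 14.7, were left out. Each gene was represented by its probe set with the highest mean, which gave 9195 genes for testing. A fold change given here is on the log2(value + pseudocount) scale and understates the change of genes with low signal. The tests were made in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in 1 fit of all 8 groups. The 13 comparisons, including 3 interaction contrasts, were taken from that fit. P-values were adjusted over the genes by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Errors beside log2 fold changes are standard errors of the fit, and errors beside signals are SDs. Sets of genes were tested with camera of limma at a preset correlation between genes of 0.01, with 24 gene lists, and camera p-values were adjusted over the 24 lists within each comparison. Overlaps between lists of called genes were tested with Fisher's exact test, two-sided, with the 9195 tested genes as the background.

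Samples were grouped by virus and by treatment as the labels give them. There were 3 arrays in each group except for wild-type PGC1 with estradiol, which had 2. The grouping, the tests, the gene lists, the rule for the genes named and the other settings to be tried were chosen before the data were examined. Under that rule, PPARGC1A, PPARGC1B, ESRRA and ESR1 were reported first. For the comparisons of 2x9 and of wild type with β-galactosidase, and of estradiol in β-galactosidase cells, the rule took the 10 called genes with the highest and the 10 with the lowest log2 fold change, and up to 4 members with the smallest p of each gene list. For every other comparison it took up to 5 called genes in each direction, and for overlaps up to 5 per pair of directions. Not every gene the rule allowed is printed. Metallothionein and GSTM genes, SLC30A1 and the genes raised by estradiol and lower with 2x9 were chosen after their values were seen.

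The analysis steps were tested on simulated data in which 200 of the 9195 genes were changed. For 2x9 against β-galactosidase, 52.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 3-fold were called, with 9 false calls. For estradiol in β-galactosidase cells the shares were 52.2%, 95.5% and 100%, with 4 false calls. For the interaction of estradiol with 2x9 they were 25.4%, 74.6% and 92.4%, with 12 false calls. A simulated shift of 1.25-fold in the 51 cell cycle genes was called by camera for estradiol in β-galactosidase cells (adjusted p = 1.38e-24), together with 1 list that had not been shifted. The simulated genes varied independently of each other and had no replicate effect. The simulation therefore does not show how reliable list calls are where genes are correlated.

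The labels number the replicates 1 to 3 in each group. Whether equal numbers pair arrays across groups was checked by correlating deviations from the group means. Equal numbers correlated at 0.169 to 0.360 for estradiol in β-galactosidase cells, 0.106 to 0.199 for estradiol in L2L3 cells, 0.132 to 0.196 for 2x9 against L2L3 and 0.247 to 0.404 for wild type against 2x9. All of these exceeded 0.1, so the numbers were taken as pairing the arrays in those 4 comparisons, and a fit with the replicate number as a block was set beside the fit without it. In the other comparisons at least 1 pair lay below that value, or only 2 pairs existed. Equal numbers of different groups still correlated above 0 in every case (lowest 0.0176), so the numbers may pair the arrays there too. The main counts come from the fit without the block.

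The other settings tried were quantile normalization, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, every probe set tested on its own, the mean of a gene's probe sets, the replicate block, a fit of only the groups compared, eBayes without the trend, each array left out in turn and, for gene lists, a correlation between genes estimated from the data. Leaving out each array in turn for the gene lists, and for the overlap of estradiol in β-galactosidase cells with wild type against L2L3, was added after seeing the data.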

Results

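MCF-7 breast cancer cells were kept in estrogen-free medium and infected with an adenovirus at a multiplicity of infection of 50, and 12 h later were treated with vehicle or 10 nM estradiol for 12 h. The viruses carried β-galactosidase as a control, wild-type PGC1, or 1 of a pair of PGC1 variants called 2x9 and L2L3. PGC-1α is a transcriptional coactivator, 2x9 is a variant engineered to favor estrogen-related receptor α (ERRα), and L2L3 carries mutations in the motifs that bind nuclear receptors. The study concerned cross-talk between ERRα and estrogen receptor α, and the design text describes 3 independent experiments. Each of the 8 combinations of virus and treatment had 3 arrays, except wild type with estradiol, which had 2. Arrays are named below by virus, treatment and replicate number.

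The first principal component held 40.6% of the variance between arrays and the second 8.16%. The ratio of 3' to 5' signal of GAPDH, a sign of RNA quality, lay between 0.780 and 0.985 on all arrays, and the ratio of actin between 0.792 and 1.03. Correlations across probe sets were 0.972 to 0.987 between arrays of 1 group and 0.938 to 0.988 between all arrays. The array β-galactosidase vehicle 2 stood apart on the second component (24.4) and had the highest median signal (47.6), and β-galactosidase estradiol 2 came next on that component (17.7), with every other array at 7.83 or less. Leukocyte markers had a median signal of 25.1 in β-galactosidase vehicle cells, with none of the 11 measured genes above 200 (0 genes, highest ITGAM at 75.7). Basal and mesenchymal markers had a median of 36.2, with 1 of 15 above 200 (CDH3, 490 ± 89.5, n = 3). Luminal epithelial markers had a median of 735, led by the keratin KRT18 at 9347 ± 478.

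The ESRRA transcript, which encodes ERRα, was higher with 2x9 and with wild type. In vehicle, ESRRA signal was 244 ± 10.2 with β-galactosidase, 650 ± 33.3 with 2x9, 604 ± 22.9 with wild type and 215 ± 33.5 with L2L3 (SD, n = 3 each). With estradiol it was 239 ± 21.3, 506 ± 46.0, 528 ± 69.7 (n = 2) and 192 ± 39.6. ESRRA rose 2.56-fold with 2x9 (log2 1.36 ± 0.13, limma adjusted p = 4.95e-08) and 2.38-fold with wild type (adjusted p = 1.47e-07). Its log2 fold change with L2L3 was -0.18 ± 0.13 (adjusted p = 0.567). A second ESRRA probe set read 71.2 ± 9.57 with β-galactosidase, 188 ± 21.7 with 2x9, 163 ± 39.7 with wild type and 67.4 ± 19.7 with L2L3. The brightest probe set of ESR1, the gene of estrogen receptor α, read 735 ± 104 with β-galactosidase, 552 ± 137 with 2x9 and 668 ± 119 with L2L3. ESR1 was called in no comparison (for 2x9, log2 -0.42 ± 0.18, adjusted p = 0.0909). The only probe set of PPARGC1A, the PGC-1α gene, stayed between 0.8 and 7.4 on every array, so it checks nothing of the transcripts made from the viruses. PPARGC1B had no probe set of its own symbol.

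**Figure D1:**
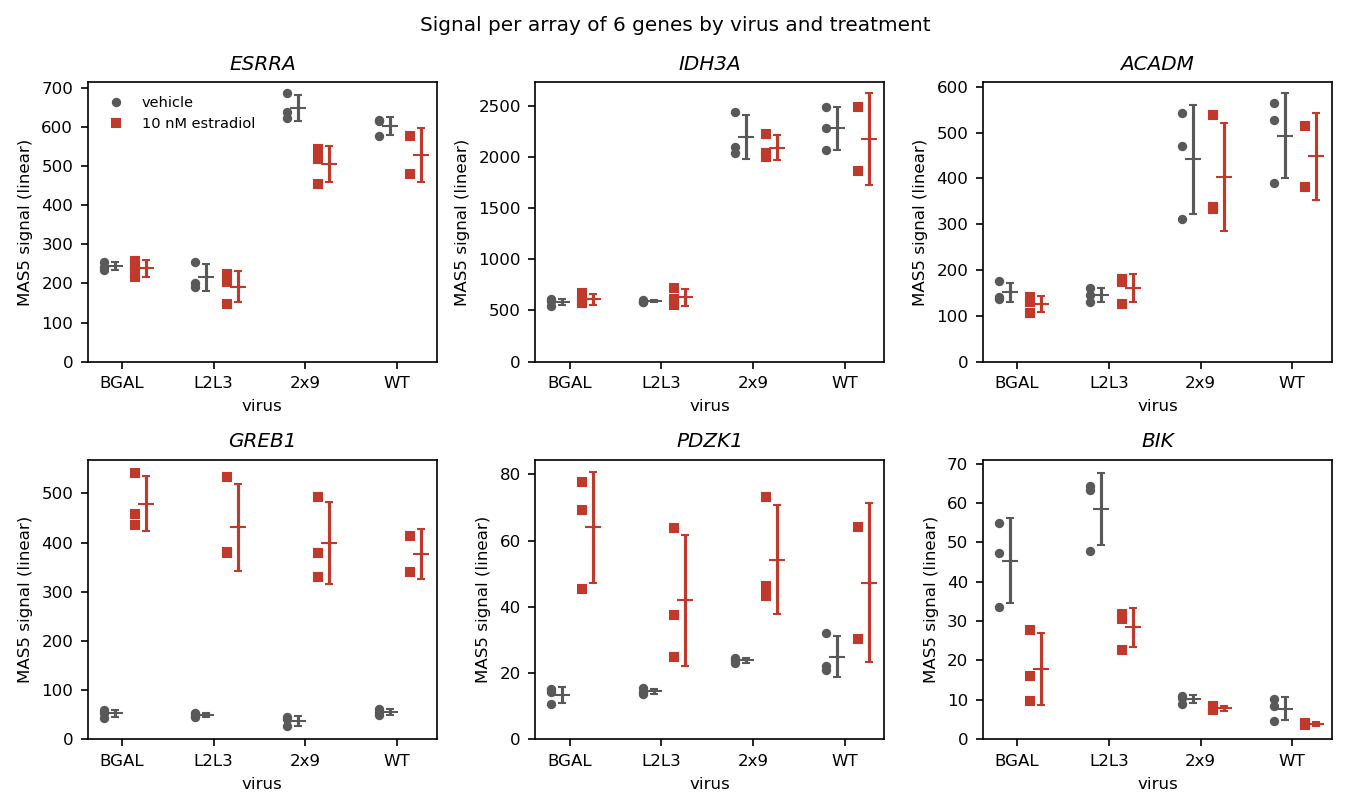
MAS5 signal per array for ESRRA, IDH3A, ACADM, GREB1, PDZK1 and BIK, grouped by virus and treatment. Points are arrays and bars are the mean ± SD; ESRRA lay at 244 with β-galactosidase and at 650 with 2x9 in vehicle, and GREB1 at 52.1 without and 479 with estradiol in β-galactosidase cells.

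The comparison of 2x9 with β-galactosidase in vehicle asked what a coactivator directed at ERRα changed without estradiol. Genes of mitochondrial energy metabolism rose together. Of 20 measured genes of the TCA cycle, 18 rose and none fell (0 genes), with a median log2 fold change of 1.01. They included IDH3A, a subunit of isocitrate dehydrogenase, at 3.68-fold (583 ± 32.6 to 2195 ± 216, log2 1.88 ± 0.11) and MDH1, malate dehydrogenase, at 2.50-fold (1.32 ± 0.07). Of 64 genes of oxidative phosphorylation, 52 rose and none fell (0 genes, median 0.58), including the complex I subunit NDUFA8 (log2 1.88 ± 0.12) and the ATP synthase subunit ATP5MC3 (1.02 ± 0.10). Of 21 genes of fatty acid β-oxidation, 14 rose and 1 fell (median 0.65), with the carnitine carrier SLC25A20 at 1.56 ± 0.15 and the carnitine palmitoyltransferase CPT1A at 1.26 ± 0.17. Of 46 mitochondrial ribosome genes, 19 rose (median 0.26), with MRPL34 at 1.69 ± 0.13, and of 31 genes of mitochondrial import and transcription, 11 rose and 1 fell (median 0.19), with the import subunit TIMM22 at 1.21 ± 0.13. Of 12 genes known as targets of ERRα, 7 rose, including ACADM, a dehydrogenase of medium-chain fatty acids, at 1.43 ± 0.20 and MAOB at 1.63 ± 0.27, and 9 of the 12 also belonged to another list. Adjusted over the list alone, the counts higher were 18 for TCA cycle, 55 for oxidative phosphorylation, 16 for β-oxidation, 23 for mitochondrial ribosome, 12 for import and 9 for ERRα targets, and the counts lower were 1 for β-oxidation, 2 for mitochondrial ribosome and 1 for import. By camera, the adjusted p-values were 1.1e-19, 2.7e-26, 2.2e-09, 9.2e-09, 0.00069 and 8.3e-07 in the same order. All 6 calls held with an estimated correlation (0.00061, 0.0067, 0.00037, 0.0055, 0.0067 and 0.0011).

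**Figure D2:**
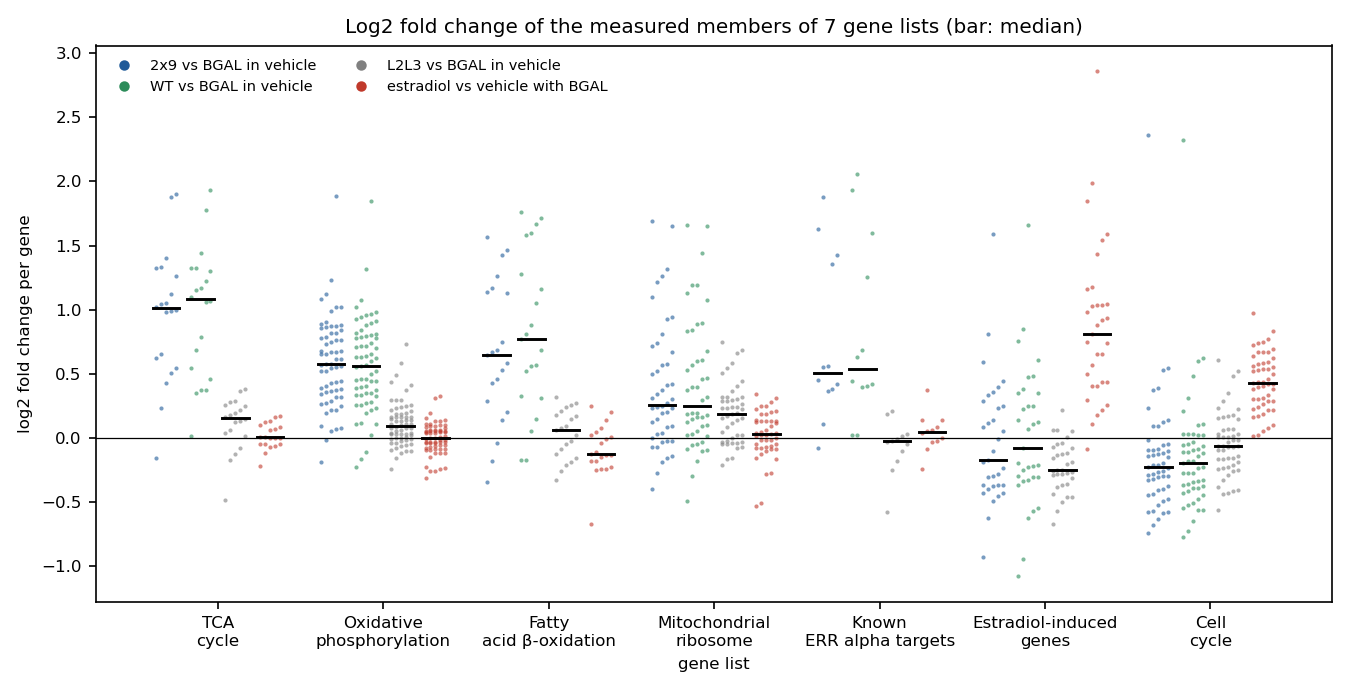
Log2 fold change of the measured members of 7 gene lists with 2x9, wild type or L2L3 against β-galactosidase in vehicle, and with estradiol in β-galactosidase cells. Points are genes and the bar is the list's median, which was 1.01 for TCA cycle with 2x9 and 0.43 for cell cycle with estradiol.

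In all, 2086 of 9195 genes (22.7%) were called with 2x9, 1032 higher and 1054 lower, of which 253 were higher and 67 lower by more than 2-fold. At an unadjusted p under 0.05 there were 3066 genes, where chance alone would give 459.75, and the median log2 fold change of all genes was -0.05. The highest was ECM1, an extracellular matrix protein, at 52.8-fold (47.5 ± 15.1 to 3390.0 ± 1108, log2 5.72 ± 0.30, limma adjusted p = 2.24e-12). It was followed by ZNF165 (3.55 ± 0.32), the glutathione transferase GSTM4 (3.04 ± 0.17), OGDHL, an oxoglutarate dehydrogenase-like enzyme (2.98 ± 0.15), the mitochondrial pyruvate carrier subunit MPC1 (2.92 ± 0.15), the aspartate aminotransferase GOT1 (2.87 ± 0.17), the metallothionein MT1H (2.79 ± 0.39), FASTKD1 (2.77 ± 0.15) and the fatty acid hydroxylase FA2H (2.66 ± 0.14). Among the lowest were the transcription factors SOX4 (3.28-fold lower, log2 -1.71 ± 0.23), PITX1 (-1.53 ± 0.25) and HOXC13 (-1.35 ± 0.18), the kinase C substrate MARCKS (-1.57 ± 0.19) and annexin ANXA1 (-1.45 ± 0.24). EFNA1 was also called (-1.33 ± 0.41), but its adjusted p was 0.208 without β-galactosidase vehicle 1 and 0.146 without 2x9 vehicle 2. The count of called genes was 1848 without β-galactosidase vehicle 2, which lay furthest out on the second principal component.

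Further lists passed with 2x9 only at the preset correlation. In branched-chain amino acid and ketone breakdown, 4 of 16 genes rose and 1 fell, both over all genes and adjusted over the list alone (median 0.14, camera adjusted p = 0.015), with BDH1, a ketone body dehydrogenase, at 0.88 ± 0.10 and AUH at 1.23 ± 0.16. Of 17 p53 targets, 7 fell, both over all genes and adjusted over the list alone (median -0.37, adjusted p = 0.0079), with the repair protein DDB2 at -1.06 ± 0.17 and the death receptor FAS at -0.90 ± 0.15. In the cell cycle list 2 of 51 genes rose and 9 fell (median -0.23, adjusted p = 0.030), where AURKA, a mitotic kinase, rose 5.14-fold (2.36 ± 0.17) and RRM1, MCM6 and CDK1, of DNA synthesis and mitotic entry, fell (-0.63 ± 0.10, -0.74 ± 0.16 and -0.52 ± 0.12). In glycolysis and hypoxia response 9 of 29 rose and 2 fell (median 0.08, adjusted p = 0.030), with the aldolase ALDOC at 2.38 ± 0.11 and the hexokinase HK1 at 0.81 ± 0.10. Of 15 luminal epithelial markers, 1 rose and 4 fell (median -0.35, adjusted p = 0.030), with the tight junction gene CLDN3 at -0.88 ± 0.12 and the cadherin CDH1 at -0.55 ± 0.09. Adjusted over the list alone, the cell cycle list had 2 higher and 9 lower, glycolysis 11 and 4, and luminal markers 1 and 7. With an estimated correlation, the adjusted p-values of these lists were 0.17 for branched-chain breakdown, 0.15 for p53 targets, 0.65 for cell cycle, 0.17 for glycolysis and 0.17 for luminal markers. The cell cycle call ended without β-galactosidase vehicle 1 (0.13), 2x9 vehicle 2 (0.19) or 2x9 vehicle 3 (0.055), the luminal call without the same arrays (0.11, 0.082 and 0.055), and the glycolysis call without 2x9 vehicle 1 (0.053).

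The other 13 lists did not pass with 2x9. Among estradiol-induced genes 2 of 33 rose and 3 fell (camera adjusted p = 0.86), with the carbonic anhydrase CA12 at 3.01-fold (1.59 ± 0.25) and the small heat shock protein HSPB8 at 0.81 ± 0.19. Among 11 estradiol-repressed genes 1 rose and 5 fell (0.21), with the cytochrome CYP1A1 at 1.88 ± 0.20, the apoptosis gene BIK at -1.22 ± 0.19 and the cyclin CCNG2 at -1.28 ± 0.21. Higher and lower counts were 2 and 4 of 18 for reactive oxygen defence (0.59), 2 and 1 of 7 for heme synthesis (0.79), led by the first enzyme of that pathway, ALAS1, at 1.96 ± 0.15, and 2 and 1 of 10 for striated muscle genes (0.30), with the creatine kinases CKMT2 at 1.23 ± 0.14 and CKB at 1.22 ± 0.16. They were 4 and 4 of 23 for sterol and fatty acid synthesis (0.39), 2 and 1 of 29 for interferon response (0.59), where the RNA sensor IFIH1 was at 1.89 ± 0.23, and 0 and 1 of 12 for NF-κB and inflammatory genes (0.21). They were 3 and 3 of 23 for unfolded protein and stress response (0.79), 2 and 3 of 12 for heat shock proteins (0.59), 0 and 4 of 39 for cytosolic ribosomal proteins (0.061), 0 and 0 of 15 for basal and mesenchymal markers (0.54), and 1 and 0 of 11 for leukocyte markers (0.54). Heme synthesis had a median of -0.10 and a mean of 0.12 with an upward test, and striated muscle a median of -0.04 and a mean of 0.18 with an upward test. The ribosomal list passed without 2x9 vehicle 1 (0.033) or β-galactosidase vehicle 2 (0.015), and NF-κB without β-galactosidase vehicle 2 (0.048).

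Wild-type PGC1 raised the same kinds of genes. With wild type against β-galactosidase in vehicle, 18 of 20 TCA cycle genes rose (median 1.08), with IDH3A at 3.83-fold (1.94 ± 0.11), as did 52 of 64 of oxidative phosphorylation (0.56), with NDUFA8 at 1.85 ± 0.12, and 15 of 21 of β-oxidation (0.77), with CPT1A at 1.71 ± 0.17 and the thiolase ACAA2 at 1.58 ± 0.18. Among mitochondrial ribosome genes 21 of 46 rose and 2 fell (0.25), among import genes 11 of 31 rose and 1 fell (0.24), and 7 of 12 ERRα targets rose (0.54), with ACADM at 1.60 ± 0.20 and MAOB at 2.05 ± 0.27. Of the p53 targets 9 of 17 fell (median -0.49), with FAS at -0.98 ± 0.15. Adjusted over the list alone, 19 TCA cycle, 57 oxidative phosphorylation and 9 ERRα target genes were higher. The camera adjusted p-values were 1.1e-19, 3.8e-24, 8.4e-12, 5.3e-09, 0.00039 and 3.3e-07 for the 6 lists that rose, all past the threshold with an estimated correlation (highest 0.0080). For p53 targets it was 0.0018 (adjusted p = 0.084 with an estimated correlation).

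In total 2297 of 9195 genes (25.0%) were called with wild type, 1074 higher and 1223 lower, 279 and 79 of them by more than 2-fold. The highest were ECM1 (45.4-fold, 2888 ± 833, log2 5.50 ± 0.30, limma adjusted p = 3.65e-12), ZNF165 (3.55 ± 0.32), GSTM4 (3.13 ± 0.17), the metallothioneins MT1H (3.07 ± 0.39) and MT1X (2.97 ± 0.51), MPC1 (2.96 ± 0.15) and GOT1 (2.90 ± 0.17). The lowest were the death receptor TNFRSF21 (-1.85 ± 0.44), HOXC13 (-1.62 ± 0.18), SOX4 (-1.59 ± 0.23), ENC1 (-1.56 ± 0.27) and TNFRSF11B, the gene of osteoprotegerin (-1.52 ± 0.32). Cytosolic ribosomal proteins had 10 of 39 genes lower (median -0.16, camera adjusted p = 0.0052), a call that ended with quantile normalization (0.35), without wild type vehicle 2 (0.086) and with an estimated correlation (adjusted p = 0.50 with an estimated correlation). Of the other 16 lists, estradiol-induced genes had 4 of 33 higher and 5 lower (0.71, with a median of -0.08 and an upward test), and heme synthesis and leukocyte markers had medians (-0.06 and -0.11) opposite to their means (0.04 and 0.15). Without β-galactosidase vehicle 3, 13 lists passed in place of 8. The cell cycle list passed without β-galactosidase vehicle 3 (0.028) or wild type vehicle 1 (0.032), branched-chain breakdown without those arrays or β-galactosidase vehicle 1 (0.041, 0.033 and 0.031), and NF-κB genes without β-galactosidase vehicle 3 (0.047). Glycolysis passed without β-galactosidase vehicle 1 (0.042), β-galactosidase vehicle 3 (0.041) or wild type vehicle 2 (0.038), and with quantile normalization (0.030). Luminal markers passed without β-galactosidase vehicle 2 (0.028), β-galactosidase vehicle 3 (0.041) or wild type vehicle 1 (0.030).

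L2L3 against β-galactosidase in vehicle showed how cells with a PGC1 variant that binds nuclear receptors poorly compared with control infection. Of 9195 genes 196 were called (2.13%), 140 higher and 56 lower, and 10 higher and 3 lower by more than 2-fold. CCNP, a cyclin-related gene, fell 2.30-fold (123 ± 15.9 to 44.0 ± 2.84, log2 -1.20 ± 0.20, limma adjusted p = 0.0026). TRMT2A, a tRNA methyltransferase, was higher (1.24 ± 0.23, adjusted p = 0.0070), with an adjusted p of 0.061 without β-galactosidase vehicle 2, and HAMP, the gene of hepcidin, was lower (-0.93 ± 0.18, adjusted p = 0.0090), with 0.061 without β-galactosidase vehicle 3. Mitochondrial ribosome genes were higher (6 of 46, 13 adjusted over the list alone, median 0.19, camera adjusted p = 8.4e-08) and p53 targets lower (5 of 17, 10 adjusted over the list alone, median -0.40, adjusted p = 8.4e-08), and both calls held with an estimated correlation (0.015 and 0.015). Both medians lay close to those with 2x9 against the same β-galactosidase arrays (0.26 for mitochondrial ribosome). Gene lists were not tested for 2x9 against L2L3, so the shifts of these lists cannot be credited to binding of nuclear receptors. The count of genes depended on single arrays, at 33 without β-galactosidase vehicle 2, 70 without β-galactosidase vehicle 3, 66 without L2L3 vehicle 3 and 21 without L2L3 vehicle 2, and it was 49 with only these groups in the fit.

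A further 6 lists passed with L2L3 at the preset correlation alone. These were oxidative phosphorylation with 1 of 64 genes higher (4 adjusted over the list alone, median 0.09, camera adjusted p = 0.00052), mitochondrial import with 2 of 31 higher (4 adjusted over the list alone, 0.018) and TCA cycle with 0 of 20 (1 adjusted over the list alone, 0.15, 0.021). Estradiol-induced genes had 0 of 33 called and a median of -0.25 (0.00052), NF-κB genes 0 of 12 and -0.22 (0.021), and basal and mesenchymal markers 0 of 15 and -0.22 (0.046). In the order given, the adjusted p-values were 0.48, 0.080, 0.48, 0.14, 0.42 and 0.48 with an estimated correlation. Quantile normalization ended the calls of TCA cycle (0.066), import (0.064), NF-κB genes (0.053) and basal markers (0.12). Without β-galactosidase vehicle 2, oxidative phosphorylation was at 0.16, import at 0.079, TCA cycle at 0.26 and basal markers at 0.44. Without L2L3 vehicle 1, TCA cycle was at 0.13, NF-κB genes at 0.12 and basal markers at 0.13, NF-κB genes were at 0.72 without β-galactosidase vehicle 1, and cytosolic ribosomal proteins passed without L2L3 vehicle 2 (0.042).

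Against L2L3 in place of β-galactosidase, 2x9 called 1610 genes, 800 higher and 810 lower, and wild type called 1951, 876 higher and 1075 lower. ESRRA was 2.90-fold higher with 2x9 (log2 1.53 ± 0.13, limma adjusted p = 8.47e-09) and 2.70-fold higher with wild type (1.43 ± 0.13, adjusted p = 2.23e-08), n = 3 each. ECM1 rose by a log2 fold change of 5.77 ± 0.30 and 5.55 ± 0.30, and MPC1 by 2.79 ± 0.15 with 2x9. The proapoptotic gene BIK fell from 58.5 ± 9.25 with L2L3 to 10.1 ± 1.00 with 2x9 (2.84-fold lower) and 7.77 ± 2.87 with wild type (log2 -1.65 ± 0.19). PPL, the gene of periplakin, fell with 2x9 (-1.28 ± 0.15), and TNFRSF11B fell with wild type (-1.70 ± 0.32). The count for 2x9 was 1047 without 2x9 vehicle 2.

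Wild type and 2x9 were compared directly in vehicle to ask whether favoring ERRα changed what PGC1 did. No gene passed (0 of 9195 by limma, smallest adjusted p = 0.223), with 301 genes at an unadjusted p under 0.05, where chance alone would give 459.75. With the replicate block 0 genes passed too. ESRRA was 604 ± 22.9 with wild type and 650 ± 33.3 with 2x9 (log2 -0.10 ± 0.13). Over the 2655 genes called for either against β-galactosidase, the median absolute difference was 0.10 and the median margin of the 95% interval on either side 0.30. For 2599 of them (97.9%) the interval lay within 1 log2 unit of 0. Comparisons that shared no array, wild type against β-galactosidase and 2x9 against L2L3, had 651 genes higher in both (93.4 by chance), 516 lower in both (108 by chance) and 0 in opposite directions. Their log2 fold changes correlated at 0.77 across genes, which are not independent replicates.

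Estradiol in cells with the β-galactosidase virus raised the genes known to follow estrogen in this line. GREB1, an early estrogen-responsive gene, rose 7.27-fold (52.1 ± 7.69 to 479 ± 56.2, n = 3 each, log2 2.86 ± 0.16, limma adjusted p = 8.76e-11). It was followed by the insulin-like growth factor binding protein IGFBP4 (1.99 ± 0.25), OLFM1 (1.85 ± 0.19), TSKU (1.65 ± 0.23), the transcription factor EGR3 (1.59 ± 0.19), the neuropeptide Y receptor NPY1R (1.54 ± 0.28), the scaffold protein PDZK1 (1.43 ± 0.23), the carbonic anhydrase CA2 (1.22 ± 0.12), the fatty acid elongase ELOVL2 (1.18 ± 0.21) and cathepsin D, CTSD (1.18 ± 0.18). Lower were the proapoptotic gene BAK1 (588 ± 18.9 to 299 ± 35.5, -0.95 ± 0.12), ID3, an inhibitor of DNA binding (-0.99 ± 0.17), and TACC1 (-0.91 ± 0.13). BIK was lower as well (-0.88 ± 0.19, adjusted p = 0.016), with adjusted p-values of 0.072 without β-galactosidase vehicle 1, 0.0503 without β-galactosidase estradiol 1, 0.078 without β-galactosidase vehicle 3 and 0.12 without β-galactosidase estradiol 2. Of 33 estradiol-induced genes 20 rose (24 adjusted over the list alone, median 0.81, camera adjusted p = 5.1e-44), and of 11 estradiol-repressed genes 1 fell (5 adjusted over the list alone, median -0.28, adjusted p = 5.4e-06). In the cell cycle list 10 of 51 genes rose and 32 did so adjusted over the list alone, all 51 had a positive log2 fold change (median 0.43, adjusted p = 6.6e-27), and the clamp loader RFC3 was at 0.70 ± 0.12. These 3 calls held with an estimated correlation (4.0e-06, 0.0056 and 0.0056).

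With estradiol in β-galactosidase cells 129 genes were called, 95 higher and 34 lower, 20 and 2 of them by more than 2-fold, and 1018 had an unadjusted p under 0.05. With the replicate number as a block the count was 280. It was 58 without β-galactosidase vehicle 3, 56 without β-galactosidase estradiol 3, 65 without β-galactosidase vehicle 2, 62 without β-galactosidase estradiol 2 and 58 with only these groups in the fit. Cytosolic ribosomal proteins passed with none of 39 genes called (0 genes, 10 higher adjusted over the list alone, median 0.14, camera adjusted p = 5.2e-07). That call ended with quantile normalization (0.93) and with an estimated correlation (adjusted p = 0.30 with an estimated correlation). The other 20 lists did not pass, including TCA cycle and oxidative phosphorylation, where IDH3A was at 583 ± 32.6 without estradiol and MDH1 had a log2 fold change of 0.10 ± 0.07. Branched-chain breakdown passed without β-galactosidase estradiol 1 (0.017), and NF-κB genes passed without β-galactosidase vehicle 3 (0.0056) or β-galactosidase vehicle 2 (0.0046).

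**Figure D3:**
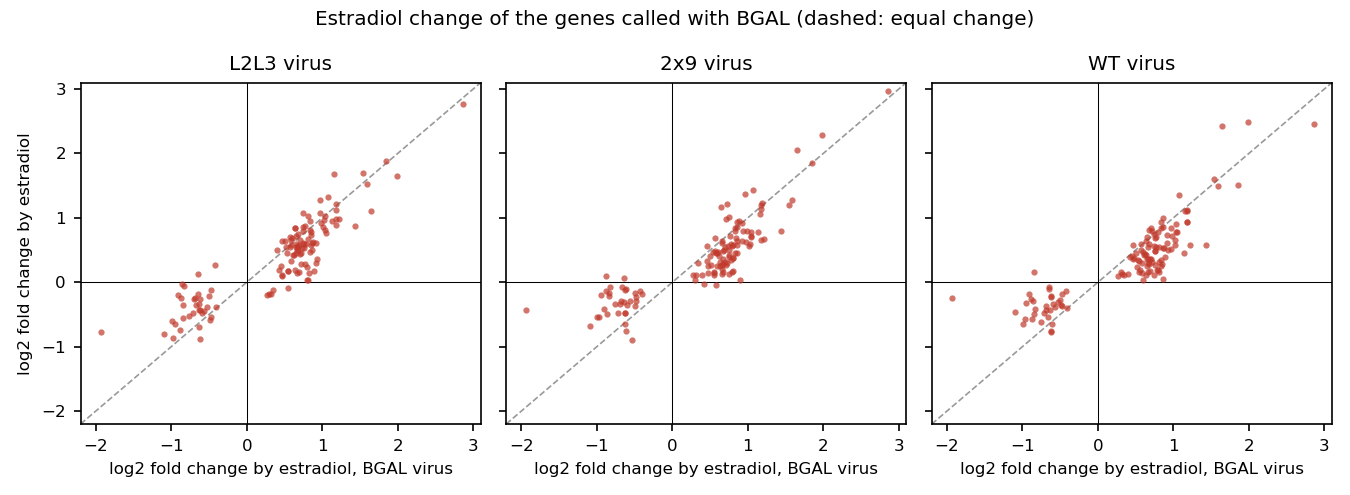
Log2 fold change with estradiol of the 129 genes called in β-galactosidase cells (horizontal axis) against the change in L2L3, 2x9 and wild-type cells (vertical axes). Points are genes and the dashed line marks equal change; 122, 125 and 128 of the 129 had the same sign.

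Whether the variants altered the response to estradiol was tested by interaction. Of the 10 genes raised most by estradiol in β-galactosidase cells, some passed with every virus and others did not. Choosing genes by their change or call in β-galactosidase cells favors large changes there. GREB1 was at 2.77 ± 0.16 in L2L3, 2.97 ± 0.16 in 2x9 and 2.45 ± 0.18 in wild-type cells, and IGFBP4 at 1.65 ± 0.25, 2.29 ± 0.25 and 2.49 ± 0.28. OLFM1 rose by 1.88 ± 0.19, 1.86 ± 0.19 and 1.51 ± 0.21, and TSKU by 2.05 ± 0.23 in 2x9 and 2.43 ± 0.26 in wild-type cells. In L2L3 cells TSKU was at 1.10 ± 0.23 (limma adjusted p = 0.010, 0.083 without L2L3 estradiol 2). PDZK1, at 1.43 ± 0.23 in β-galactosidase cells, was at 0.88 ± 0.23 in L2L3 cells (limma adjusted p = 0.043), a call that ended without L2L3 vehicle 1 (0.094), 2 (0.14) or 3 (0.13) or L2L3 estradiol 1 (0.092) or 2 (0.27). PDZK1 did not pass in 2x9 cells (0.80 ± 0.23, limma adjusted p = 0.18) or wild-type cells (0.58 ± 0.25, adjusted p = 0.63). CA2, at 1.22 ± 0.12 in β-galactosidase cells, rose by 0.98 ± 0.12 in L2L3 and 0.67 ± 0.12 in 2x9 cells and did not pass in wild-type cells (0.59 ± 0.13, adjusted p = 0.060). NPY1R did not pass in 2x9 cells (1.20 ± 0.28, adjusted p = 0.056), but did without 2x9 vehicle 1 (0.029) or 2x9 estradiol 2 (0.018). In L2L3 cells MYBL1 rose by 1.68 ± 0.15 and the transcriptional repressor CIC changed by -0.90 ± 0.17. In 2x9 cells the protease PRSS23 rose by 1.43 ± 0.18 and PIK3R3, a regulatory subunit of PI 3-kinase, changed by -0.90 ± 0.11. By limma, estradiol called 197 genes in L2L3 cells (130 higher, 67 lower), 42 in 2x9 cells (35 and 7) and 26 in wild-type cells (24 and 2), the last with 2 estradiol arrays. No gene passed in the interaction of estradiol with 2x9, wild type or L2L3 (0 genes each by limma, with 347, 244 and 609 at an unadjusted p under 0.05). Chance alone would give 459.75 at that unadjusted p, so the counts for 2x9 and wild type lay below chance. With the replicate block 0 genes passed in each interaction as well. Over the 129 genes, the 95% interval of the difference from β-galactosidase cells had a median margin on either side of 0.44 for 2x9, 0.47 for wild type and 0.44 for L2L3, and lay within 1 log2 unit of 0 for 106, 101 and 111 genes. Genes called in both β-galactosidase and L2L3 cells numbered 56 higher and 10 lower (1.34 and 0.248 by chance), with 2x9 28 and 3 (0.362 and 0.0259), and with wild type 20 and 2 (0.248 and 0.0074), and 0 were opposite in each.

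The count in L2L3 cells was 384 with the replicate block, where the overlap with β-galactosidase cells was 93 higher and 27 lower. The 56 genes higher in both became 35 without β-galactosidase vehicle 3, 31 without β-galactosidase estradiol 3, 36 without L2L3 vehicle 2 or β-galactosidase estradiol 2 and 31 without L2L3 estradiol 2. The count in L2L3 cells was 114 without L2L3 estradiol 1, 100 without L2L3 vehicle 3, 87 without L2L3 vehicle 2 and 77 without L2L3 estradiol 2. In 2x9 cells the count was 26 without 2x9 vehicle 3 and 27 without 2x9 vehicle 2, and in wild-type cells it was 10 without wild type estradiol 1, 13 without wild type estradiol 2 and 14 without wild type vehicle 2. Leaving out the same wild-type arrays in that order took the 20 genes higher in both to 9, 11 and 13. As lists, the change of cell cycle genes with estradiol was smaller in 2x9 than in β-galactosidase cells for 47 of 51 genes (median difference -0.18, camera adjusted p = 1.13e-05, adjusted p = 0.562 with an estimated correlation). Cytosolic ribosomal proteins had a median difference of -0.08 (adjusted p = 0.0152, 0.671 with an estimated correlation), a call that ended with quantile normalization (0.462) and without 2x9 vehicle 1 (0.099), 2x9 estradiol 1 (0.20), β-galactosidase estradiol 3 (0.16), 2x9 estradiol 3 (0.064) or β-galactosidase vehicle 2 (0.290). The interaction with L2L3 called 1 gene without β-galactosidase vehicle 3 and 6 without L2L3 estradiol 2. The genes lower with estradiol in both were as few as 2 with L2L3, 0 with 2x9 and 0 with wild type when 1 array was left out.

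The other 22 lists did not pass in the interaction of estradiol with 2x9, and none passed with wild type (0 lists). Estradiol-induced genes such as GREB1 had a camera adjusted p of 0.13 for 2x9 and passed without β-galactosidase estradiol 1 (0.0062) or 2x9 estradiol 3 (0.0046). TCA cycle genes passed for 2x9 without 2x9 vehicle 1 (0.025) or 2x9 estradiol 2 (0.032), and oxidative phosphorylation without β-galactosidase vehicle 3 (0.041), β-galactosidase estradiol 2 (0.012) or 2x9 estradiol 2 (0.011). Import genes and ERRα targets passed without 2x9 estradiol 2 (0.043), NF-κB genes without β-galactosidase vehicle 3 (0.015) or 2 (0.021), and basal markers without 2x9 vehicle 2 (0.039). For wild type, cell cycle genes were at 0.066 and passed without β-galactosidase vehicle 1 (0.015), β-galactosidase estradiol 1 (0.0027), wild type vehicle 3 (0.035), β-galactosidase vehicle 2 (0.038), wild type vehicle 2 (0.016) or wild type estradiol 2 (0.0087). Estradiol-induced genes were at 0.12 for wild type and at 0.0027 without β-galactosidase estradiol 1. Sterol synthesis genes passed without wild type estradiol 1 (0.0017) or wild type vehicle 2 (0.016), and NF-κB genes without β-galactosidase vehicle 3 (0.033) or 2 (0.038).

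The overlap of estradiol with the ERRα-directed variant was tested between estradiol in β-galactosidase cells and 2x9 against L2L3 in vehicle, which share no array. Lower in both were 9 genes (3.00 by chance, Fisher's exact p = 0.0021, Benjamini-Hochberg 0.0045), among them TACC1 (log2 -0.91 ± 0.13 with estradiol and -1.02 ± 0.13 with 2x9). Higher in both were 11 (8.27 by chance, Fisher's exact p = 0.36), including HSPB8 (1.04 ± 0.19 and 0.95 ± 0.19) and CA2 (1.22 ± 0.12 and 0.90 ± 0.12). Raised by estradiol and lower with 2x9 were 13 (8.37 by chance, Fisher's exact p = 0.10), including the fatty acid binding protein FABP5 (0.83 ± 0.13 and -0.78 ± 0.13) and the DNA polymerase subunit POLA2 (0.85 ± 0.16 and -0.66 ± 0.16). Lowered by estradiol and higher with 2x9 were 4 (2.96 by chance, Fisher's exact p = 0.53), including PRR15L (-0.76 ± 0.14 and 0.56 ± 0.14). Log2 fold changes of the comparisons correlated at -0.05 across genes. Every pair of directions, opposite ones included, lay above chance. Fisher's exact test takes the genes as independent and equally likely to be called, which was not tested. The 9 genes lower in both became 5 without β-galactosidase vehicle 1, β-galactosidase estradiol 1, 2x9 vehicle 3, L2L3 vehicle 3 or L2L3 vehicle 2, 3 without β-galactosidase estradiol 2 or 3, and 2 without β-galactosidase vehicle 2 or 3. The 11 higher in both became 6 without β-galactosidase estradiol 2 and 7 without L2L3 vehicle 1, β-galactosidase vehicle 2 or 3, or β-galactosidase estradiol 3. The 13 became 8 without L2L3 vehicle 1 or 2x9 vehicle 2 or 3, and 5 without β-galactosidase vehicle 2 or 3 or β-galactosidase estradiol 2 or 3. The 4 became 2 without L2L3 vehicle 1, 2x9 vehicle 3 or β-galactosidase estradiol 3, and 1 without β-galactosidase vehicle 3. With the replicate block the counts were 42 lower in both, 25 higher in both, 33 raised by estradiol and lower with 2x9, and 15 the other way.

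The same overlap with wild type against L2L3, which was not chosen in advance, had 16 genes raised by estradiol in β-galactosidase cells and higher with wild type (9.05 by chance, Fisher's exact test, Benjamini-Hochberg p = 0.040). Lower in both were 10 (3.97 by chance, Fisher's exact test, Benjamini-Hochberg p = 0.0086). Raised by estradiol and lower with wild type were 14 (11.1 by chance, 0.47), and lowered by estradiol and higher with wild type were 6 (3.24 by chance, 0.20). Every pair of directions again lay above chance, so the same limit of the test applies. The 16 became 10 without β-galactosidase vehicle 2 or 3 or β-galactosidase estradiol 2, and 9 without β-galactosidase estradiol 3. The 10 became 6 without wild type vehicle 1 or β-galactosidase estradiol 1, 4 without β-galactosidase estradiol 3, 3 without β-galactosidase vehicle 3 or estradiol 2, and 2 without β-galactosidase vehicle 2. The 14 became 5 or 6 without any of the L2L3 vehicle arrays, wild type vehicle 2, β-galactosidase vehicle 2 or 3, or β-galactosidase estradiol 2 or 3. The 6 became 4 without L2L3 vehicle 1, L2L3 vehicle 3 or wild type vehicle 2, 3 without β-galactosidase vehicle 2, and 2 without β-galactosidase vehicle 3 or estradiol 3.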

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

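Tests of scaling, single arrays, correlation between genes and regrouped arrays as causes were chosen after the results were seen, while the list tests, quantile normalization and the estimated correlation had themselves been chosen before the data were examined. The change of the cell cycle list with estradiol was smaller in 2x9 cells than in β-galactosidase cells (median difference -0.18, camera adjusted p = 1.13e-05 over 24 lists). Its median estradiol change by replicate number was 0.28, 0.43 and 0.56 in β-galactosidase cells and 0.09, 0.31 and 0.40 in 2x9 cells. Scaling between arrays did not account for it (adjusted p = 3.32e-05 with quantile normalization), nor did a single array (highest adjusted p = 0.0249, without 2x9 vehicle 1). Correlation between the genes of the list remained a possible cause (adjusted p = 0.562 with an estimated correlation), so the difference is not established. The estimated correlation and the replicate block were not tried together. Over these settings the adjusted p ranged from 2.27e-08 to 0.562.

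Cytosolic ribosomal proteins had a smaller estradiol change in 2x9 than in β-galactosidase cells (camera adjusted p = 0.0152). The list's median change by replicate number was 0.07, 0.18 and 0.18 in β-galactosidase cells. In 2x9 cells it was -0.02, 0.11 and 0.08, lower at each number. In L2L3 cells it was lower still (-0.19, -0.04 and -0.26), so a lower change was not particular to 2x9. Wild-type cells were at 0.15 and 0.18 for numbers 1 and 2. The difference between 2x9 and β-galactosidase cells could come from scaling between arrays (adjusted p = 0.462 with quantile normalization, where the direction turned). It could also come from a single array (0.290 without β-galactosidase vehicle 2) or from correlation between the genes (0.671 with an estimated correlation). Each of these ended the call.

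The arrays of each pair of groups were also regrouped without regard to their labels, and the counts of genes or lists were taken again. For comparisons of 3 with 3 arrays only 10 splits exist, too few for a share under 0.05. The real split was 1 of the 10 splits with a count as high for 2x9 against β-galactosidase (2086 genes, highest other split 0), wild type against β-galactosidase (2297, 0), L2L3 against β-galactosidase (196, 0), 2x9 against L2L3 (1610, 0) and wild type against L2L3 (1951, 0). It was 1 of the 10 splits as well for estradiol in β-galactosidase cells (129, 1), in L2L3 cells (197, 1) and in 2x9 cells (42, 0). For wild type against 2x9, 10 of the 10 splits reached the real count of 0, and the highest other was 1. Any split reaches a count of 0, so that comparison was not decided by regrouping. For gene lists, 1 of the 10 splits reached the count for 2x9 (11 lists, highest other 9) and for L2L3 (8, highest other 6), 5 of the 10 splits for wild type (8, highest other 11) and 7 of the 10 splits for estradiol in β-galactosidase cells (4, highest other 7). Every other split mixed arrays of both groups, which leaves part of a real difference in place and adds the rest to the spread. Counts from those splits are therefore no measure of chance, and regrouping decided none of these comparisons.

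For interactions, 100 splits of 12 arrays were drawn. For estradiol with 2x9, 100 of the 100 splits reached the real count of 0 genes (highest other 1551, as drawn splits mix the infections) and 86 of the 100 splits reached the real count of 2 lists (highest other 14). For estradiol with L2L3, 100 of the 100 splits reached 0 genes (highest other 97). Any split reaches a count of 0, so the counts of genes decided nothing for the interactions. The count of lists decided nothing either, because the drawn splits mix the infections. For the overlaps this test decided nothing, because in each of the other pairs of splits at least 1 side called too few genes to share more than 1. In it, 1 of the 100 pairs of splits reached the 37 genes called both for estradiol in β-galactosidase cells and for 2x9 against L2L3 (highest other 1). Likewise 1 of the 100 pairs reached the 66 shared estradiol genes of β-galactosidase and L2L3 cells (highest other 0), and 1 of the 100 pairs reached the 31 of β-galactosidase and 2x9 cells (highest other 0). Estradiol in wild-type cells was not split, as it had a group of 2 arrays.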

How the results depend on the processing

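Tests of gene lists and of the overlap with wild type with 1 array left out were chosen after the results were seen. With pseudocount 1, genes called for estradiol in β-galactosidase cells and for 2x9 against L2L3 numbered 5 lower in both and 8 lowered by estradiol and higher with 2x9. With no filter on low values, they numbered 8 raised by estradiol and lower with 2x9, and 2 the other way. The interaction of estradiol with L2L3 called 2 genes with pseudocount 64 and 2 with a stricter filter. With the replicate block the counts were 447 for L2L3 against β-galactosidase and, for estradiol, 280 in β-galactosidase, 384 in L2L3, 112 in 2x9 and 67 in wild-type cells. In their deviations, 23 of 23 arrays correlated best with their own replicate number. The mean correlation between groups was 0.18 for equal numbers and -0.09 for other numbers. Pairing may thus hold in every comparison, and the counts without the block ignore it. With the block, the overlap of estradiol with 2x9 against L2L3 was 25 higher in both, 42 lower in both, 33 raised and lower, and 15 lowered and higher. Shared estradiol genes of β-galactosidase cells were 93 higher and 27 lower with L2L3, 59 and 10 with 2x9, and 42 and 6 with wild type, and 1 list, cell cycle, passed for the interaction with wild type (0.016). With the block the glycolysis call with 2x9 ended (0.066), luminal markers passed with wild type (0.039), and it ended no other list call and none of the 409 calls of named genes (0 calls). It gave 2162 genes for 2x9 against L2L3 and 0 for wild type against 2x9. Without the trend, genes lower in both were 6 with L2L3 and 1 with wild type. With only the groups compared in the fit, the counts were 49 for L2L3 against β-galactosidase and 58, 23 and 5 for estradiol in β-galactosidase, 2x9 and wild-type cells. The 4 overlaps with 2x9 against L2L3 were then 7, 5, 3 and 2, and the shared estradiol genes 34 and 3 with L2L3, 15 and 0 with 2x9, and 5 and 0 with wild type. With an estimated correlation, lists passing numbered 6 for 2x9, 2 for L2L3 and 0 for the interaction with 2x9, and with quantile normalization 4 for L2L3 and 1 for the interaction with 2x9. The cytosolic ribosomal list turned direction in that interaction with quantile normalization (adjusted p = 0.462).

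With 1 array left out, called genes ranged from 1512 to 1898 for 2x9 against β-galactosidase, 1725 to 2070 for wild type, 21 to 227 for L2L3, 1047 to 1429 for 2x9 against L2L3, 1353 to 1703 for wild type against L2L3 and 0 to 0 for wild type against 2x9. With estradiol they ranged from 56 to 123 in β-galactosidase, 77 to 144 in L2L3, 26 to 45 in 2x9 and 10 to 26 in wild-type cells, and for interactions from 0 to 6 with L2L3 and 0 to 0 with 2x9 and wild type. The 4 overlaps ranged from 6 to 12, 2 to 8, 5 to 13 and 1 to 6, and shared estradiol genes from 31 to 52 and 2 to 7 with L2L3, 20 to 29 and 0 to 3 with 2x9, and 9 to 21 and 0 to 2 with wild type. Lists passing ranged from 9 to 13 for 2x9, 8 to 13 for wild type, 4 to 9 for L2L3, 4 to 5 for estradiol in β-galactosidase cells, 1 to 6 for the interaction with 2x9 and 0 to 2 with wild type. When a wild-type estradiol array was left out, the lone array was assumed to vary like the other groups. Of 409 calls of named genes, 12 ended with quantile normalization, 14 with pseudocount 1 (of 407), 7 with pseudocount 64, 32 without the filter, 9 with every probe set tested, 27 with the mean of probe sets, 28 without the trend, 67 with only the groups compared and 0 with the block. Leaving out 1 array ended 434 of 2447 such calls, and none turned direction (0 calls). Signals near background limit fold changes of weak genes, a p past no threshold is no proof of equality, and the cause of these changes was not tested.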

Other observations

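The tests in this part were chosen after the results were seen, except the overlap without the cell cycle list, chosen before its result, and the overlap of estradiol in β-galactosidase cells with 2x9 against L2L3, chosen before the data were examined. Probe sets shared among metallothioneins, small proteins that bind zinc and copper, were higher with 2x9 and wild type, and those with probes of their own were not. All 10 probe sets whose identifier suffix marks probes shared by several transcripts were higher with 2x9 (log2 fold change 0.99 to 3.08) and with wild type (1.03 to 3.60) against β-galactosidase in vehicle, and 0 were called with L2L3. MT2A signal went from 361 with β-galactosidase to 2152 with 2x9 and 2744 with wild type (n = 3 each). Of 7 probe sets of the glutathione transferases GSTM, which conjugate glutathione to reactive compounds, 4 were higher with both forms, and with 2x9 those 4 lay between 1.87 and 3.04. They belonged to GSTM1, GSTM2 and GSTM4, while GSTM3, GSTM5 and a second GSTM4 probe set were not called (the last at 0.52, adjusted p = 0.069 with 2x9, and 0.45, adjusted p = 0.12 with wild type). The suffix of the GSTM probe sets also marks shared probes.

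The metallothionein probe sets might not tell their genes apart, as 0 of the 4 probe sets with probes of their own were called higher with 2x9, and those lay near background apart from MT3 (53.8 to 29.0), so the test could not tell. For a zinc response through MTF1, its target SLC30A1 was not higher with 2x9 (log2 -0.14 ± 0.21, limma adjusted p = 0.709, upper 95% bound 0.303). A single target gene cannot exclude such a response, so it stays open. With 2x9, a single array did not account for the rise of the shared metallothionein probe sets tested, 1 for each gene. The smallest log2 fold change was 0.84 with each 2x9 or β-galactosidase vehicle array left out. The rise with wild type was not tested in this way.

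Genes called for estradiol in L2L3 cells had smaller median changes in 2x9 than in β-galactosidase cells. The 130 raised genes had medians of 0.70 in L2L3, 0.53 in β-galactosidase, 0.40 in 2x9 and 0.44 in wild-type cells, and the 67 lowered genes -0.62, -0.23, -0.12 and -0.24. A lower estradiol response with 2x9 could not be told from correlation between genes (Benjamini-Hochberg p = 0.0932 for raised and 0.0744 for lowered genes by camera with an estimated correlation, both 0.000267 at the preset one). Choosing genes by their call in L2L3 favors large changes there.

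Of the 130 genes raised by estradiol in L2L3 cells, 38 were lower with 2x9 than with β-galactosidase in vehicle (14.9 by chance) and 10 higher (14.6 by chance). With wild type 43 were lower (17.3 by chance, Benjamini-Hochberg p = 3.64e-08 by Fisher's exact test). Of the 67 genes lowered by estradiol there, 18 were lower with 2x9 too (7.68 by chance, Benjamini-Hochberg p = 0.000897 by Fisher's exact test) and 13 higher (7.52 by chance). For all 38 genes the log2 fold change with 2x9 was lower against β-galactosidase than against L2L3. Vehicle signal with L2L3 thus also lay below that with β-galactosidase, so low values of these genes were not particular to 2x9. MCM6 was at 0.75 with estradiol in L2L3 cells and -0.74 with 2x9 against β-galactosidase, and at 0.67 and -0.68 on the other arrays (estradiol in β-galactosidase cells, 2x9 against L2L3), while KLF10 went from 0.89 and -1.28 to 0.53 and -0.64, RASGRP1 from 0.85 and -1.19 to 0.36 and -0.66, and DEK from 0.86 and -0.93 to 0.05 and -0.31 (limma adjusted p = 0.236 for the last). Only 5 of the 38 genes were in the cell cycle list. Without that list 33 remained with 2x9 (13.1 by chance, Benjamini-Hochberg p = 6.45e-07 by Fisher's exact test) and 37 with wild type (15.3 by chance, 4.90e-07). The listed genes alone thus did not account for the excess. The test covered only the 51 measured genes of the list, so it does not exclude other genes of cell division. A shared effect could not be told on the other arrays, where 13 genes were raised by estradiol and lower with 2x9 (8.37 by chance, 0.160) and 14 lower with wild type (11.1 by chance, 0.384). Over these settings and the other arrays without the cell cycle list, the adjusted p ranged from 1.05e-07 to 0.237 for 2x9 and from 3.64e-08 to 0.496 for wild type. The p-values of genes raised by estradiol and lower with 2x9 or wild type were adjusted here over 8 tests. The 0.000897 was adjusted over every overlap tested, where the 14 genes with wild type had 0.47 by Fisher's exact test.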
